A study of Rattus norvegicus with 6 samples.

How the data were processed

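Total RNA from whole hearts of 3 rats with CPB and 3 sham-operated rats was measured on 1 array per animal, and samples were assigned to groups and replicate numbers from their titles. The labels do not describe how the animals were housed, sampled or processed together. The array, its label chemistry, scanner, background correction and normalization software are not given in the sources used here.

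The deposited values are on a natural log scale, as read from the values themselves, since the labels state no unit. Within each array the hyperbolic sine of the deposited values lay on a grid of equal steps above a lowest level, to within 6.22e-06 of a step. Each value is thus the inverse hyperbolic sine, close to a natural log for values of this size, of a linear function of a whole-number spot level. What the authors did to obtain those levels is unknown. The step and the lowest level differed between arrays, and the step was 80.1 to 359.6 linear units, which sets the precision of dim probes. Probes at an array's lowest level were treated as measured values in the fit. A named gene at it on all arrays of a group has no measured level there. The 3 such genes (Cxcl1, Egr2 and Grik5) were also at it on 1 or more arrays of the other group, so no fold is given for them.

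Values were taken back to the linear scale (2 times the hyperbolic sine), quantile normalized (limma normalizeQuantiles with ties averaged) and converted to log2 with no pseudocount. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a variance trend, two-sided), with Benjamini-Hochberg adjustment over all 1185 probes and a threshold of 0.05. An exact permutation test of 3 against 3 animals cannot go below p = 0.1.

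The choice of normalization needs a caution. The rule written before the data were examined called a table normalized when the highest array median was at most 1.25 times the lowest, and it had linear values in mind. On the linear scale the ratio was 2.52, so quantile normalization became the main setting before any test was run. Read literally on the deposited log values, the ratio is 1.16 and no further normalization would have been the main setting, in which Sparc alone passes the threshold. Both are reported. The plan also foresaw a pseudocount for linear values and none for a log2 table, and none was used for this natural log table.

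Of the 1185 probes, 1113 carried 1 gene symbol, 2 carried several and were not named, and 70 are unnamed here. Symbols came from the platform annotation and were checked through gene identifiers against the rat RefSeq gene table (assembly GRCr8), which held 1106 of the 1113. They covered 1103 genes, 10 with more than 1 probe. The brightest probe stood for a gene in list tests. Probes of Cap1, Cngb1 and Pam differed in sign, none past the threshold.

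Before the data were examined, 30 gene lists with 1139 genes were written, of which 132 genes were measured. The 16 lists with at least 5 measured genes were tested with limma camera (preset correlation 0.01), adjusted over these lists. The other 14 held 0 to 4 measured genes and were not tested. These were the lists of cytokines and chemokines (3), adrenergic, muscarinic and adenosine signalling (4), glucocorticoid-induced genes (4), heat shock and chaperones (0), and apoptosis and cell death (0), and markers of endothelial cells (0), fibroblasts (2), smooth muscle and pericytes (3), neutrophils and monocytes (1), macrophages (2), lymphocytes (4), mast cells (3), erythroid cells and platelets (0) and adipocytes (0). A further 10 lists were written after the gene names and some values had been seen and are described with the other observations.

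Named genes followed a rule fixed beforehand. It takes up to 12 probes per direction with the largest difference among those past the threshold whose groups do not overlap, and fills each direction to 6 by the smallest unadjusted p among probes whose groups do not overlap. It adds the 3 members with the smallest p in each tested list, and 25 genes fixed in advance, of which 3 were measured. This gave 58 names. Other members named for a list were picked as examples after their values were seen.

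Replicate numbers were shared between groups, so their pairing was checked. Deviations from the group means correlated at 0.240, 0.277 and 0.296 across probes for CPB and sham arrays numbered 1, 2 and 3. All were above 0.1, so the numbers may pair the samples. The main fit and the main list test used no pairing, so their SEs, intervals and p-values ignore it. A pairing would rest on the data alone, since the labels name no shared litter, day or batch. In the values as deposited the 3 correlations were 0.0584, 0.300 and 0.442, so number 1 fell short of 0.1 there. The fit with the number as a block was run as an alternative and is given beside a result where it changes the call.

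The alternatives fixed beforehand were the values as deposited, median scaling, a pseudocount at the 25th percentile, a floor at the 10th percentile, the brighter 593 probes, no variance trend, a robust variance estimate, array weights, the replicate block, each array left out in turn, a threshold of 0.1, an estimated correlation or fry for the lists, and the mean over a gene's probes. Added after the data were seen were a common floor, the step size as a covariate, quantile normalization on the log scale, filters on probes at the lowest level (498 or 916 probes kept) alone or joined to other scalings, and the matrix list without Sparc. Some of these had been tried in a first look at the data, which is why all are listed.

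The fit was tested on simulated data, with 200 of 1185 probes changed in each of 20 simulations of CPB against sham. Probes were set at their mean deposited values (converted to log2), with the real steps and lowest levels. Spreads were the moderated SDs of the limma fit and not each probe's own SD, so the shares below are not those for the probes' own spreads. Among probes of the brighter part, 20.6% of log2 changes of 1 were called, 45.2% of 1.5, 68.1% of 2 and 81.0% of 3. Among the dimmer ones, the shares were 19.7%, 42.0%, 45.5% and 49.1%. Of all calls, 3.34% were false. The simulation changed 200 probes at once, so its shares do not carry over to a design where few probes change. It also drew noise independently for each probe and array. Deviations shared by arrays of the same number were not modelled, so its shares of calls and of false calls may not hold for these arrays. Figures were drawn with matplotlib 3.10.9.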

Results

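Total RNA from whole rat hearts was measured on an array of 1185 probes, 1 array per heart. The hearts came from 3 animals that underwent cardiopulmonary bypass (CPB, in which a pump and oxygenator take over circulation and gas exchange) and 3 sham-operated controls. The labels name cardiac inflammation and cytokines as the subject, so the comparison asks which cardiac transcripts differ after bypass. They do not give the time of sampling or the length of bypass.

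Each array had a lowest level below which no value was listed. The share of probes at that level ran from 10.7% on CPB replicate 2 to 47.3% on CPB replicate 3, and 498 of the 1185 probes lay above it on all 6 arrays. The median deposited value, converted to log2, ran from 8.51 on CPB replicate 1 to 9.84 on sham replicate 3. With 3 arrays in each group, their number limits the precision of every difference below.

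**Figure D1:**
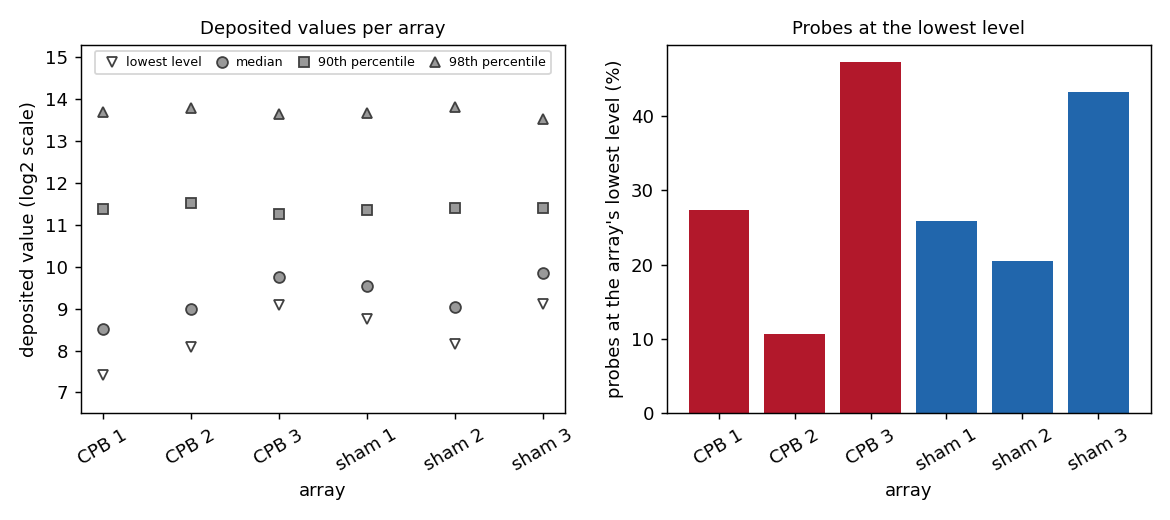
Left, the lowest level, median, 90th and 98th percentile of the deposited values of each array (converted to log2) against the array. Right, the percentage of probes at the array's own lowest level, with CPB in red and sham in blue. The 98th percentiles lay between 13.53 and 13.80, whereas the lowest levels ran from 7.42 to 9.12.

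No single gene passed the adjusted threshold of 0.05 between CPB and sham hearts. The smallest adjusted p belonged to Sparc (probe RA1307), which encodes the matricellular protein osteonectin. Its normalized log2 intensity was 13.14 ± 0.66 (SD, n = 3) in CPB hearts and 14.64 ± 0.17 (SD, n = 3) in sham hearts. The difference was -1.50 (SE 0.33, 95% interval -2.20 to -0.81; limma adjusted p = 0.371), and all 3 CPB values lay under all 3 sham values. Sparc was lower in all 23 alternatives and passed the threshold in 5. Those 5 included the values as deposited, without further normalization (-1.40, limma adjusted p = 0.0328), and the fit without CPB replicate 1 (-1.83, limma adjusted p = 0.00135). CPB replicate 1 held the CPB value nearest to the sham values (13.82). Sparc did not pass after median scaling (-1.01, limma adjusted p = 0.934) or with the replicate number as a block (limma adjusted p = 0.724). Without any other single array it also missed the threshold (limma adjusted p from 0.603 to 0.918).

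Next to Sparc on the lower side, 5 genes had the smallest unadjusted p among probes whose groups did not overlap, and none passed the threshold (limma adjusted p = 0.909 for each). Dbp, a clock-controlled transcription factor, had a log2 difference of -0.98 (SE 0.32), with 10.28 ± 0.36 (SD, n = 3) in CPB and 11.25 ± 0.25 (SD, n = 3) in sham hearts. Dusp7, a phosphatase of MAP kinases, differed by -1.04 (SE 0.36) and Lyc2, a lysozyme, by -0.85 (SE 0.32). Dusp7 lay only 1, 4 and 1 steps above the lowest level on CPB replicates 1, 2 and 3, and 5, 5 and 2 on the sham replicates. Lim2, known as a lens membrane protein, differed by -0.72 (SE 0.24) and Tcf3, a basic helix-loop-helix transcription factor, by -0.78 (SE 0.28). For both of these, 2 of the 3 CPB arrays were at their lowest level.

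On the higher side, the 6 probes chosen by the same rule also missed the threshold (limma adjusted p = 0.909 for each). Ugdh, which makes the glucuronic acid precursor of glycosaminoglycans, had a log2 intensity of 11.20 ± 0.10 (SD, n = 3) in CPB and 10.20 ± 0.47 (SD, n = 3) in sham hearts, a difference of 1.00 (SE 0.33). Ugdh lay 11, 29 and 5 steps above the lowest level on CPB replicates 1, 2 and 3, and 2, 11 and 2 on the sham replicates. Pla2g2a, a secreted phospholipase A2 of acute inflammation, was at 11.90 ± 0.84 (SD, n = 3) in CPB and 10.91 ± 0.06 (SD, n = 3) in sham hearts, a difference of 0.98 (SE 0.37). Its value on CPB replicate 1 (10.99) lay next to the highest sham value (10.98), and without CPB replicate 2 the difference was 0.60. Furin, a proprotein convertase, differed by 0.86 (SE 0.37) and Hnrnpa1, an RNA-binding protein, by 0.58 (SE 0.27). Furin lay 4, 9 and 2 steps above the lowest level on CPB replicates 1, 2 and 3, and 1, 4 and 0 on the sham replicates. The unnamed probes RA0678 and RA0357 differed by 0.85 (SE 0.32) and 0.66 (SE 0.29).

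**Figure D2:**
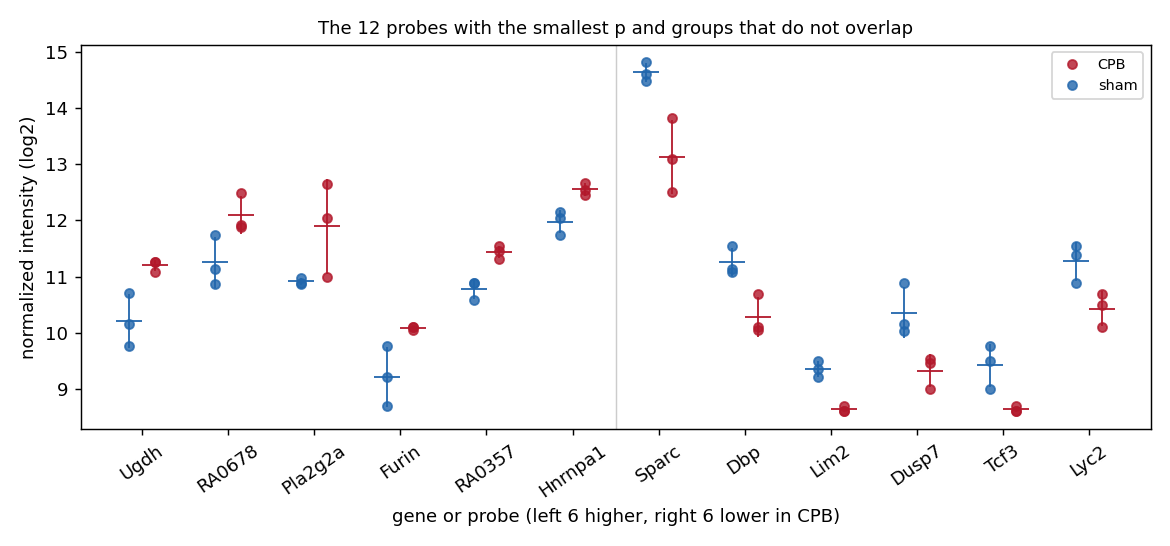
Normalized log2 intensity of the 6 higher and 6 lower probes in each heart, with CPB in red and sham in blue. Points are single hearts, and bars give the mean and SD of 3. None of the 12 passed the limma adjusted threshold, and the widest gap in means was that of Sparc, 13.14 in CPB and 14.64 in sham hearts.

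The limma fit called 0 of 1185 probes, and 35 had an unadjusted p under 0.05, where 59.25 would be expected by chance for arrays without shared structure. Of these 35, 10 were higher and 25 lower in CPB hearts, so 28.6% were higher. That share was 15.2% in the values as deposited (7 higher and 39 lower) and 55.0% with arrays scaled to the same median (11 higher and 9 lower), and it also moved with single arrays and with the block. It was 57.1% without CPB replicate 1 (12 higher and 9 lower), 50% without CPB replicate 2, 51.2% without CPB replicate 3, 47.2% without sham replicate 2 and 9.5% without sham replicate 3 (4 higher and 38 lower). With the replicate number as a block it was 44.7% (17 higher and 21 lower), so no balance of directions can be read from these probes. The median log2 difference over all probes was -0.03, against -0.29 as deposited and 0.11 after median scaling. Groups did not overlap for 50 probes (4.22%), where chance gives 10% for exchangeable arrays without ties. Shared replicate numbers and ties at the lowest level break that condition here. In the 3 other splits of the arrays that part all 3 numbers, 20 to 29 probes had an unadjusted p under 0.05 and 37 to 44 had groups apart.

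Of 25 stress and inflammation genes named before the data were examined, 3 were measured under a symbol of their own. Cxcl1, a chemokine that attracts neutrophils, was at the lowest level on all 3 sham arrays and on CPB replicates 1 and 3. On CPB replicate 2 it lay 17 steps above it, so a single heart carries its difference (limma adjusted p = 0.909). No fold is given, since the other 5 arrays hold no measured level. Socs3, an inhibitor of cytokine signalling, was at 10.45 ± 0.36 (SD, n = 3) in CPB and 9.76 ± 0.73 (SD, n = 3) in sham hearts. The difference was 0.69 (SE 0.39, limma adjusted p = 0.909), with 0.44 without sham replicate 1 and 1.09 without sham replicate 2. Socs3 lay only 1, 10 and 1 steps above the lowest level on sham replicates 1, 2 and 3, and 4, 14 and 4 on the CPB replicates. Myh6, the alpha myosin heavy chain of heart muscle, differed by -0.10 (SE 0.30), by 0.29 in the values as deposited and by 0.69 after median scaling, so its sign depended on the scaling. After quantile normalization it held either 17.70 or 18.01 on each array, set by its rank among the brightest probes. The -0.10 therefore records rank alone.

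Of 16 lists tested, the extracellular matrix and remodelling genes were the only one past the threshold, lower in CPB hearts with a median log2 difference of -0.24 (limma camera adjusted p = 0.0231). The call was lost with a correlation estimated for the list (limma camera adjusted p = 0.439), with the replicate number as a block (adjusted p = 0.0817) and after median scaling (adjusted p = 0.118). It was also lost without Sparc (adjusted p = 0.303) and without sham replicate 1, 2 or 3 (adjusted p = 0.242, 0.111 and 0.0893). It passed in 13 of 23 alternatives tested with camera (adjusted p from 0.00123 to 0.439), among them the values as deposited (median -0.53, adjusted p = 0.00416) and the brighter probes (median -0.51, adjusted p = 0.00123). The limma fry test, which asks whether the list moves at all and not whether it differs from other genes, gave an adjusted p of 0.0422 for a shift in 1 direction and 0.274 for mixed directions. Of the 14 measured genes, 11 were lower, 2 were higher and 1 was equal. Sparc was the only member past the threshold when p was adjusted over the list alone (limma adjusted p = 0.00438), and 0 members passed over all probes. The basement membrane chain Lamb2 differed by -0.64 (SE 0.31), elastin (Eln) by -0.62 (SE 0.48), and the small proteoglycans Dcn and Bgn by -0.51 (SE 0.44) and -0.49 (SE 0.34). The brain proteoglycan Bcan differed by -0.75 (SE 0.38), and the cell surface proteoglycans Sdc4 and Cspg4 by 0.40 (SE 0.38) and 0.25 (SE 0.40). Of the 14 genes, 8 lay above the lowest level on all arrays.

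**Figure D3:**
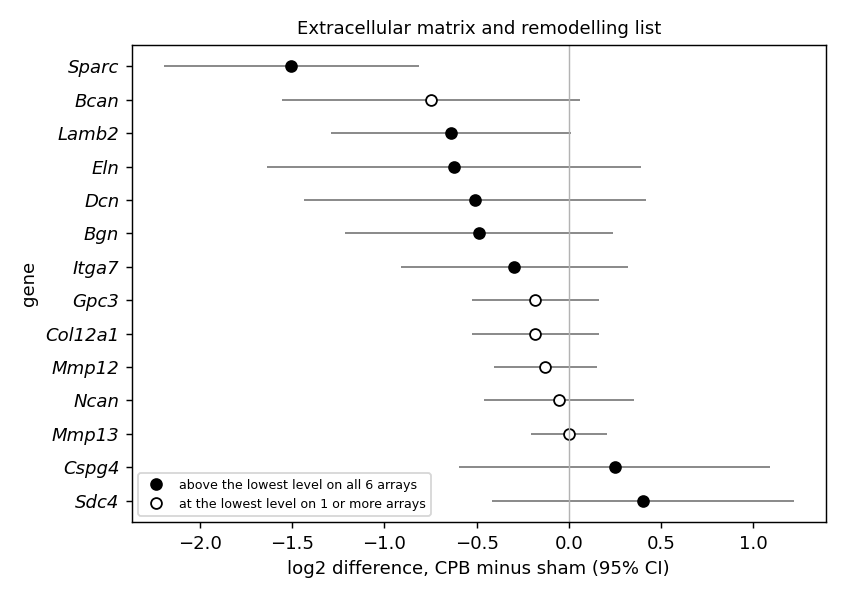
Log2 difference between CPB and sham hearts (x axis, CPB minus sham) for the 14 measured genes of the extracellular matrix and remodelling list, with limma 95% intervals. Filled points lay above the lowest level on all 6 arrays, and open points lay at it on 1 or more. The interval of Sparc, -2.20 to -0.81, was the only one of the 14 without 0.

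In the inflammation lists, no member passed the threshold, over all probes or adjusted over the list alone. Of 6 adhesion and acute inflammatory mediators, 2 were higher and 4 lower (median -0.32, and 0.028 after median scaling; limma camera adjusted p = 0.728). They included Pla2g2a, the coagulation initiator F3 (tissue factor) at -0.68 (SE 0.35) and the complement component C1qb at -0.38 (SE 0.28), which was 0.07 after median scaling. Of 8 cytokine and chemokine receptors and signalling genes, 5 were higher and 3 lower (median 0.02, with -0.36 as deposited, limma camera adjusted p = 0.728). Stat5a stood at -0.32 (SE 0.24) and Il1rap at -0.22 (SE 0.31). Tlr4, Il1rl1 and Tnfrsf11b, counted among the 5 higher, were each at the lowest level on 2 CPB and 3 sham arrays. Each differed by 0.02, the same as the list median, so they show no measured rise. Of 9 immediate-early genes, 3 were higher and 6 lower (median -0.14, and 0.15 after median scaling; adjusted p = 0.728). Dusp1 stood at -0.71 (SE 0.40), Dusp6 at 0.39 (SE 0.36), and Egr2 lay at the lowest level on all CPB arrays and 2 sham arrays. Dusp1 lay only 1, 10 and 1 steps above the lowest level on CPB replicates 1, 2 and 3, and 2, 6 and 4 on the sham replicates.

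Muscle and energy genes also stayed short of the threshold. The 6 contractile and sarcomere genes had a median of 0.11, and of 0.54 after median scaling (limma camera adjusted p = 0.606), with cardiac troponin I (Tnni3) at 0.47 (SE 0.28), Tpm2 at 0.19 (SE 0.35) and Dmd at -0.16 (SE 0.35). Of the 8 calcium handling and calcium signalling genes, 7 were lower (median -0.19, with -0.42 as deposited and -0.025 after median scaling, adjusted p = 0.606), while Casq2, the calcium store protein of the sarcoplasmic reticulum, was at 0.38 (SE 0.33). Camkk2 and Atp2b3 were each at the lowest level on 2 CPB arrays, and on 1 and 2 sham arrays. Of the 12 hypoxia and glycolysis genes, 6 were higher, 4 lower and 2 equal (median 0.00, with -0.24 as deposited and 0.16 after median scaling, adjusted p = 0.606). Among them Pfkfb3, which raises glycolytic flux, was at 0.72 (SE 0.34), Hif1a at 0.55 (SE 0.32) and Gapdh at -0.33 (SE 0.29), which was 0.09 after median scaling. Hif1a lay only 2, 5 and 1 steps above the lowest level on CPB replicates 1, 2 and 3, and 1, 1 and 0 on the sham replicates. The 7 mitochondrial oxidation and fatty acid genes had a median of -0.03, and of 0.39 after median scaling, with a camera direction of up (adjusted p = 0.998), and Ckm, muscle creatine kinase, was at -0.47 (SE 0.31) and at 0.11 after median scaling. Cox6c was at 0.13 (SE 0.29) and Mdh1 at 0.10 (SE 0.28). The 6 antioxidant and metal response genes also differed in sign between median and camera direction (adjusted p = 0.998). Their median was -0.06, with -0.26 as deposited and 0.13 after median scaling. Among them Fth1 was at 0.29 (SE 0.33), Prdx1 at -0.28 (SE 0.39, and 0.10 after median scaling) and Gsta1 at -0.19 (SE 0.36).

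Channel, signalling and neural lists gave the same outcome. Kcnk3, a background potassium channel, was at -0.65 (SE 0.30) among 8 potassium, sodium and chloride channels (median -0.06, with -0.51 as deposited and -0.12 after median scaling, limma camera adjusted p = 0.606), in which Kcnn3 was at -0.25 (SE 0.18) and Kcnc2 at -0.13 (SE 0.13). The 8 neurotransmitter receptor and synaptic genes had a median of -0.20, with -0.66 as deposited and -0.26 after median scaling (adjusted p = 0.606), and Grik5, Slc32a1 and Vamp1 were at the lowest level on 3, 2 and 2 CPB arrays and on 1, 1 and 2 sham arrays. The 7 kinase and phosphatase genes had a median of 0.07, with -0.057 as deposited and 0.34 after median scaling (adjusted p = 0.606). Among them Cdk5r1 was at 0.53 (SE 0.34), Pdpk1 at 0.24 (SE 0.32, and -0.32 as deposited) and Map3k12 at -0.18 (SE 0.16). The 5 growth factor and receptor genes had a median of 0.13, and of -0.31 as deposited (adjusted p = 0.617), with Irs2 at 0.25 (SE 0.31), Nrg1 at 0.15 (SE 0.24; -0.31 as deposited) and Fgfr2 at -0.12 (SE 0.21). The 5 load and natriuretic genes had a median of 0, with -0.21 as deposited and 0.18 after median scaling, and a mean of 0.05 (adjusted p = 0.623), with Npr2 at 0.29 (SE 0.31), Ctf1 at 0.28 (SE 0.25; -0.21 as deposited) and Agt at -0.27 (SE 0.35).

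Markers of the cell types a heart can hold did not pass either. The 6 cardiomyocyte markers had a median of -0.19, with 0.046 as deposited and 0.44 after median scaling (limma camera adjusted p = 0.766), with phospholamban (Pln) at -0.28 (SE 0.27) and at 0.19 after median scaling. The 7 nerve and glia markers had a median of -0.13, with -0.35 as deposited and 0.046 after median scaling (adjusted p = 0.606). Among them Prph was at -0.54 (SE 0.33), Gfap at -0.28 (SE 0.29, and 0.046 after median scaling) and Sox10 at -0.18 (SE 0.16). The fibroblast list held only Sparc and Dcn, which also belong to the matrix list. S100a9, the single neutrophil and monocyte marker measured, was at 10.56 ± 0.97 (SD, n = 3) in CPB and 11.63 ± 0.79 (SD, n = 3) in sham hearts, a difference of -1.07 (SE 0.47, limma adjusted p = 0.909), with overlapping groups. The lymphocyte marker Cd8a was at 0.92 (SE 0.47) and Cd3d at -0.15 (SE 0.37), the macrophage markers C1qb and Aif1 at -0.38 (SE 0.28) and -0.02 (SE 0.31), and the smooth muscle markers Tagln and Myh11 at 0.65 (SE 0.45) and -0.21 (SE 0.28). These marker genes outside the tested lists were named after their values were seen, and none passed the threshold.

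Of the 58 genes named by rule, 39 reversed, came to 0 or moved by more than 1.5 times when 1 array was left out, so the size of a single difference is uncertain. Several genes named above had arrays at the lowest level that are not given beside them. Sox10, Map3k12, Fgfr2, Kcnn3 and Kcnc2 were at it on 2 CPB and 2 sham arrays, Stat5a on 2 CPB and 1 sham, and Nrg1 and Ctf1 on 1 CPB and 2 sham. Irs2, Pdpk1 and Aif1 were at it on 1 array of each group, F3, Il1rap and Bcan on 1 CPB array, Furin and Hif1a on 1 sham array, and Cdk5r1 on 2 sham arrays.

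Correlations between arrays covered overlapping ranges within groups (0.895 to 0.945) and between groups (0.887 to 0.961). Across probes, which are not independent replicates, Pearson's r averaged 0.921 over the 3 pairs of CPB arrays, 0.904 over the 3 pairs of sham arrays and 0.916 over the 9 pairs between groups. Pairs between groups that shared a replicate number averaged 0.932, and the others 0.908. The first principal component held 31.9% of the variance and set both arrays numbered 3 (scores of 7.99 and 11.28) apart from the other 4 (-6.23 to -3.50).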

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

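The step covariate, the common floor, log-scale quantile normalization, the filters on the lowest level and the list without Sparc were chosen after seeing the data. Of 1246 comparisons of a named gene with an alternative, 1204 kept direction and side of the threshold and 7 came to exactly 0. Another 30 reversed and 5 gained a call, all for Sparc. Median scaling gives each array a single factor, so it moved every deposited difference by the same amount (Sparc from -1.40 to -1.01). Apart from Myh6, already positive as deposited, its reversals came from that common shift. The shift was set by the array medians (8.51 to 9.84 in log2), whereas the 98th percentiles were 13.53 to 13.80. Causes of the other reversals and of the gained calls were not tested. Sparc was lower in all 23 alternatives (-1.83 to -1.01) and passed in 5, with limma adjusted p from 0.00135 to 0.934. Signal over the lowest level limits dim genes, and 687 probes lay at it on at least 1 array.

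The count of called probes was 1 in place of 0, that probe being Sparc, as deposited, with the robust variance estimate (adjusted p = 0.0268), with probes at the lowest level on 3 or fewer arrays (adjusted p = 0.0467) and with that filter and log-scale quantile normalization (adjusted p = 0.0263). With the filter on deposited values it was 0. Leaving out each array gave 0 to 1 calls. Probes at an unadjusted p under 0.05 numbered 35, against 20 with median scaling, 53 with array weights, 22 among the 498 probes above the lowest level (fewer were tested) and 21 to 72 with an array left out (21 without CPB replicate 1, 72 without sham replicate 2). With the replicate block the fit called 0, with 38 at an unadjusted p under 0.05.

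The matrix list was lower in all 23 camera alternatives and passed in 13, with adjusted p from 0.00123 to 0.439. Directional fry, which does not set it against other genes, gave an adjusted p of 0.0422. No list passed, so the count was 0 in place of 1, with median scaling (median -0.13), the replicate block (median -0.24, adjusted p = 0.0817), the step size as a covariate (-0.22, adjusted p = 0.104), the common floor (-0.24, adjusted p = 0.0672), that floor joined to the filter (-0.52, adjusted p = 0.0648), the estimated correlation (-0.24, adjusted p = 0.439) and mixed fry (-0.24, adjusted p = 0.274). Its median without Sparc was -0.18 (adjusted p = 0.303). Leaving out each array gave 0 to 1 lists and a median of -0.31 to -0.15. The replicate block changed no other call. The 15 other lists stayed short of the threshold in all 271 comparisons, but 21 of their medians moved by more than the spread between arrays, and 10 lists turned sign with the scaling, while the load list, at 0, took both signs. Mean r within groups was 0.913 over all probes and 0.895 over the brighter ones.

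Reversals as deposited, with and without the filter, were Ctf1 (-0.21), Pdpk1 (-0.32), Nrg1 (-0.31) and Myh6 (0.29). With median scaling they were C1qb (0.067), Prdx1 (0.10), Gapdh (0.093), Ckm (0.11), Pln (0.19), Gfap (0.046) and Myh6 (0.69). Nrg1 was -0.0025 with array weights. The common floor, with and without the filter, gave Irs2 -0.11 and Myh6 0.29. With an array left out, the ranges that crossed 0 were Fth1 (-7.27e-04 to 0.55), Cox6c (-0.060 to 0.24), Mdh1 (-0.12 to 0.23), Prdx1 (-0.64 to 0.11), Nrg1 (-0.19 to 0.29), Gsta1 (-0.36 to 0.055), Fgfr2 (-0.29 to 0.12) and, each with the same levels, Atp2b3, Map3k12 and Sox10 (-0.27 to 0.016).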

Other observations

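The tests of Sparc and the matrix list and the alternatives quoted with them were planned, apart from the list without Sparc and the step size as a covariate. The other tests in this part were written after the results they bear on had been seen, and the 10 further gene lists were written after gene names and some values had been seen. None of these lists passed, with limma camera adjusted p from 0.129 to 0.945. An extended list of 20 matrix and basement membrane genes had a median log2 difference of -0.18 (adjusted p = 0.129), with Lama3 at -0.40 (SE 0.33) and Fmod at 0.33 (SE 0.31), each at the lowest level on 1 array (CPB for Lama3, sham for Fmod). Of 30 plasma protein, complement and coagulation genes, most at or near the lowest level, the median was -0.13 (adjusted p = 0.176). The 27 membrane traffic genes had a median of 0.11 (adjusted p = 0.176), the 20 lipid oxidation and acyl-CoA genes 0.08 (adjusted p = 0.185) and the 8 tropomyosin and troponin genes 0.11 (adjusted p = 0.185), of which 7 were higher, Tpm3 by 0.70 (SE 0.40).

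The 11 nuclear pore genes had a median of -0.01 (limma camera adjusted p = 0.555), with Nup107 at -0.90 (SE 0.40) and Nup153 at 0.62 (SE 0.36). The 10 natural killer cell receptor genes (adjusted p = 0.555), 18 ribosomal protein genes (adjusted p = 0.786) and 17 postsynaptic scaffold genes (adjusted p = 0.945) had medians of 0.00, -0.07 and 0. The 8 circadian clock genes had a median of 0.12 with a camera direction of down (adjusted p = 0.945). Among them Per2 was at -0.37 (SE 0.35) and Bmal1 at 0.24 (SE 0.27). Dbp had a limma adjusted p of 0.0625 over that list alone, against 0.909 over all probes. The list was written after some values had been seen, and Dbp was among the probes named for a small p. The 0.0625 is therefore no support. Per2 was at the lowest level on 1 CPB array, and Bmal1 on 1 CPB and 2 sham arrays.

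Sparc (log2 difference -1.50, limma adjusted p = 0.371) and the matrix list (camera adjusted p = 0.0231) were lower in CPB hearts. The call of the list was lost with an estimated correlation (adjusted p = 0.439), under the replicate block (adjusted p = 0.0817) and after median scaling (adjusted p = 0.118). Fewer fibroblasts in the CPB hearts may account for part of it and stays open. The other stromal matrix genes above the lowest level on all arrays (Dcn, Bgn and Eln) are themselves members of the matrix list. Their lower values restate that result and cannot tell fewer fibroblasts from lower expression. Their mean was -0.54, but the interval of Eln reached -1.64, beyond the -1.50 of Sparc. Earlier forms of this test gave -0.29 over 5 genes, dim ones included, and -0.75 for the most extreme pair of arrays, which by itself would have argued against fibroblasts. Whether Sparc alone moves the list is also undecided, since without it the adjusted p was 0.303 and the median still -0.18, and an effect of bypass itself is untested beyond the comparison.

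In the values as deposited, 77.3% of probes were lower in CPB hearts, with a median log2 difference of -0.29. Lowest levels that differ between the arrays are an explanation that the values go with. Over the 402 probes at the lowest level on 3 or more arrays the median was -0.49, equal to the difference of the mean lowest levels. That match is no support, since the 41 probes at the lowest level on all arrays take this difference by construction. Over the 297 brightest probes the median was -0.0075 and 51.9% were lower, so the shift lay outside the bright probes. No biological explanation of this shift was tested.

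Arrays of the same number deviated together across the groups, with a mean correlation of 0.271, against at most 0.0558 in the other pairings of 6. The same-number pairing would lead by chance in 1 of 6 cases. Deviations from a group mean cancel within the group, so a high value for 1 pairing also lowers the others. Over probes above the lowest level on all arrays the smallest of the 3 correlations was 0.205. This does not decide on shared lowest levels, since those values were normalized together with probes at the lowest level. As deposited, the correlation was 0.0584 for number 1, whose CPB and sham lowest levels were 7.42 and 8.76. It was 0.300 for number 2 (8.08 and 8.16) and 0.442 for number 3 (9.08 and 9.12). A shared hybridization or exposure batch could account for the shared deviations. The step size ranked all 3 numbers alike in both groups, but chance does so in 1 of 6 orders. The labels name no batch, so this cannot be told apart from other sources such as animals handled together.

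The 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05. All 10 splits called 0 probes. For probes at an unadjusted p under 0.05, 7 of the 10 splits gave as many as the real 35, and the highest other gave 96. That split, singled out for its high count, set the 3 arrays of smaller step against the 3 of larger step. The 3 arrays of smaller step (CPB replicates 1 and 2, sham replicate 2) also had the lower lowest levels and medians. The split further kept both arrays numbered 2 together and both numbered 3 together. Step size therefore cannot be told apart from these as the source of the count. With step size as a covariate, CPB against sham gave 35 probes at an unadjusted p under 0.05 and 0 lists. Among the 4 splits that part all 3 numbers, the other 3 gave 20 to 29 probes, and splits that part fewer numbers gave 49 to 96. For lists, only the real split (1 of 10) gave 1, and the highest other gave 0.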
